A study of Mus musculus with 4 samples.

How the data were processed

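Whole back skin of 4 mice was profiled on Affymetrix whole-transcript mouse arrays, 2 mice heterozygous for Bmal1 and 2 germline knockouts. The design text calls the replicates biological littermates, so each array is 1 mouse. Per the labels' protocols, total RNA was isolated with TRIzol and RNeasy columns, amplified with the Ambion WT expression kit and labelled with biotin. Per the submitters' processing notes, Affymetrix Expression Console 1.1.1 and PLIER 2.0 were used. The deposited values are 1 table of 35557 probe sets, taken here to be on a log2 scale from their range (2.54 to 14.9); the scale and any step between arrays are not given in the sources used here. Medians of the deposited arrays were 7.46 and 7.54 for the heterozygous mice and 7.45 and 7.47 for the knockout mice. PLIER and the averaging of probes along a transcript can hide a change in part of a transcript, and a signal near background compresses differences. Arrays give no read depth, and their number limits the precision. At most 0.104% of probe sets had equal values in any 2 arrays, so each column was counted as its own sample.

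The following choices were made before the data were examined: groups, tests, thresholds, gene lists, the rule for named genes and most of the other settings listed below. The rule for scaling was to keep the deposited values if medians and quartiles of the arrays lay within 0.1 of each other, and otherwise to quantile normalize. Quartiles differed by up to 0.34, so all 4 arrays were quantile normalized. The annotation paired 21789 probe sets with 1 gene, 1621 with several and 12147 with none. Symbols of 21698 probe sets were updated through the gene identifier with a table of the GRCm38.p6 assembly, which was also used for the order of neighbouring genes. The build of the array annotation is not given in the sources used here, and no coordinates are printed. No gene was named from a probe set with several genes. Tested were the 17557 probe sets paired with a gene whose mean over the 4 arrays lay above the 25th percentile of such probe sets (6.66).

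The knockout was compared with the heterozygote with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend by mean expression), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The fit had 2 residual degrees of freedom. The SEs given are limma's moderated ones, in which each probe set's variance is drawn towards the fitted prior. They can therefore differ from the spread of a gene's own arrays. Gene lists were tested with camera at a preset correlation of 0.01 against all tested genes with 1 probe set each, the one with the highest mean, and adjusted over the 33 lists with at least 4 tested members. Of 589 list members 506 were tested. The alternatives were an estimated correlation and fry. The lists covered the clock, the cell cycle, DNA repair and stress responses, metabolism, and markers of the cell types that whole skin can hold. Named in the text are Arntl, every tested clock gene, members of each list that passed, chosen from the 4 with the smallest p, and, because no probe set passed, the 6 genes in each direction with the smallest p whose knockout arrays both lay above or both lay below the heterozygous range. Myh7, Tnnt1, members of other lists, and the genes in the closing observations were chosen after their values were seen.

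Other settings were offsets of 16 and 64 on the linear scale, median centring, no filter, a filter at the 50th percentile, eBayes without a trend or with a robust prior, the number in the labels as a replicate block, each array left out in turn, all probe sets, 1 probe set per gene, X and Y left out, and 25 or 100 neighbours. The deposited values without further scaling and a threshold of 0.10 were added after the data were seen. When an array was left out, the lone array of its genotype was assumed to vary like the pair of the other. A list's direction across settings is the sign of its median, a rule set after a first run that had used camera's direction.

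The test was checked on simulated data for the comparison of knockout with heterozygote, over 17557 probe sets of which 200 were changed. With variances drawn from limma's fitted prior, it called 1 of 67 changed by 1.5-fold, 49 of 67 changed by 2-fold and 64 of 66 changed by 4-fold. Over 20 such draws, 5.13% of the calls were unchanged probe sets. A first version of the simulation, which used each probe set's own moderated variance, gave 12.5% over 20 draws, above the nominal 5%, so the share of false calls depends on how well the prior describes these arrays. No list was called when none was shifted. A list shifted as a whole was called with the preset correlation but not with an estimated one. The simulated probe sets varied independently of each other. The check therefore cannot show how often lists are called wrongly when genes move together, nor which correlation is the better choice here.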

Results

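Gene expression was measured in whole back skin of C57Bl6 mice at postnatal day 22, when the hair follicles are in telogen, the resting phase of the hair cycle. Skin was taken at ZT22, late in the dark phase, where ZT counts hours from lights on. The 2 mice called heterozygous carried 1 mutant and 1 wild-type allele of Bmal1 (gene symbol Arntl), which encodes the transcription factor that pairs with CLOCK to drive the circadian clock. The 2 knockout mice lacked both copies in the germline. Each mouse gave 1 Affymetrix whole-transcript array, so that 4 arrays were compared, and their number limits the precision of every value below. The values are on a log2 scale, and differences are knockout minus heterozygous. The comparison asked which skin transcripts depend on Bmal1 at this time of day.

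Bmal1 itself was lower in both knockout arrays than in both heterozygous arrays. The Arntl probe set read 8.90 and 9.08 in the heterozygous arrays and 8.29 and 8.16 in the knockout arrays. The knockout mean was 58.8% of the heterozygous mean, a log2 difference of -0.76 (SE 0.12, n = 2 per genotype), with a limma adjusted p of 0.102 over all tested probe sets. The probe set averages probes along the transcript and may include probes outside the deleted part, so the remaining signal does not measure intact mRNA. Adjusted p was 0.040 with probe sets filtered at the 50th percentile and 0.010 with 1 probe set per gene. It was 0.167 without a filter, 0.155 without a trend and 0.248 with all probe sets.

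Among the clock genes, those that passed went in both directions. Of the 21 tested members of the 2 clock lists, 7 passed when adjusted over the list alone, that is over both clock lists together, and 0 passed over all tested probe sets. The genes that rose were Cry1 and Cry2, which encode repressors of CLOCK and BMAL1, Tef, a transcription factor that binds D-box elements, and Bhlhe41, a repressor that binds E-box elements. Cry1 was higher by 0.69 (SE 0.10), Cry2 by 0.47 (SE 0.10), Tef by 0.46 (SE 0.11) and Bhlhe41 by 0.93 (SE 0.23). The genes that fell were Nr1d1 and Nr1d2, which encode the nuclear receptors REV-ERB alpha and beta, and Per1, a period gene. Their log2 differences were -0.73 (SE 0.13), -0.68 (SE 0.17) and -0.42 (SE 0.10). Without heterozygous array 2 the Nr1d2 difference was -0.46, and without knockout array 1 that of Bhlhe41 was 0.62. In each of these 7 genes both knockout arrays lay above or both lay below the heterozygous range, as in 49.4% of all tested probe sets. Genes picked by a small p seldom overlap between 2 pairs of arrays, so this adds no support. Over both clock lists the adjusted p of the 7 ran from 0.0073, for Cry1, to 0.021.

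The other 14 clock genes did not pass. Usp2 differed by 0.30, Nfil3 by 0.26, Dbp by 0.24, Per2 by 0.14, Clock by 0.14, Bhlhe40 by 0.11 and Noct by 0.02. Lower values were read for Rorb (-0.31), Per3 (-0.18), Ciart (-0.18), Wee1 (-0.17), Rora (-0.16), Arntl2 (-0.12) and Hlf (-0.09). A second Ciart probe set differed by -0.48, so the 2 probe sets of this gene disagreed in size. Npas2 was not analysed here. With 1 array left out, Per2 ran from 0.03 (without heterozygous array 2) to 0.26 (without heterozygous array 1), Clock from 0.06 to 0.22 on the same arrays, Per3 from -0.28 (without heterozygous array 1) to -0.08 (without heterozygous array 2), and Arntl2 from -0.21 (without knockout array 1) to -0.04 (without knockout array 2). Without heterozygous array 2, the signs of Noct (-0.04), Bhlhe40 (-0.08), Hlf (0.11) and Ciart (0.06) turned, and without knockout array 1 that of Noct did (-0.01). Hlf was also positive after median centring (0.02). As sets, neither clock list passed camera, which asks whether a list moves one way against other genes. The list of clock activators and genes driven through ROR elements had a median difference of 0.01 over 6 tested members (adjusted p = 0.78). The list of E-box and D-box outputs had a median of 0.02 over 15 members (adjusted p = 0.86), where the test pointed the other way. Both lists passed fry's test for change in either direction, with adjusted p = 0.015 for the first and 0.032 for the second.

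**Figure D1:**
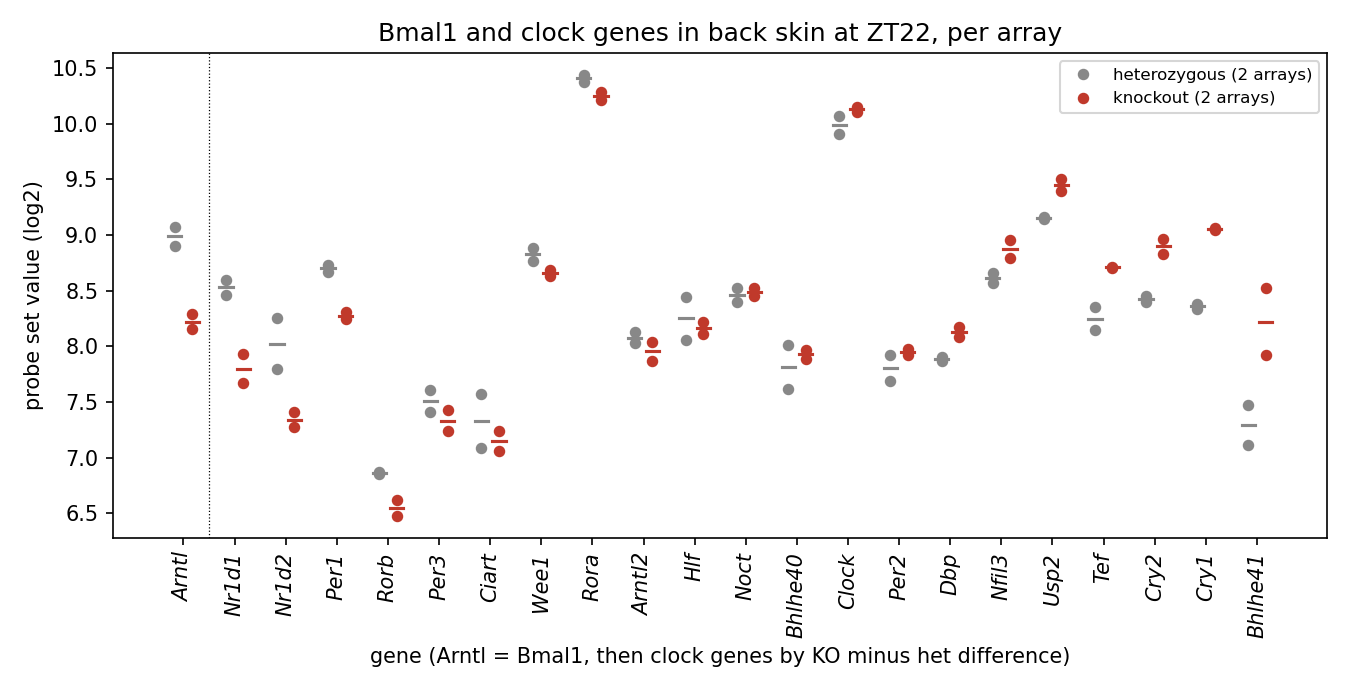
Probe set values (vertical axis, log2) of Bmal1 (Arntl) and the 21 tested clock genes (horizontal axis) in the heterozygous arrays (grey) and the knockout arrays (red). Points are single arrays and bars are means of 2 arrays per genotype. Arntl sits at 8.90 and 9.08 in the heterozygous arrays and at 8.29 and 8.16 in the knockout arrays, and clock genes run from Nr1d1, lower by 0.73, to Bhlhe41, higher by 0.93.

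Over the whole array, no single gene passed the threshold. The limma test of 17557 probe sets gave 0 at an adjusted p under 0.05. It gave 2713 at an unadjusted p under 0.05, or 15.5%, where chance gives 5% on average. That share was 6.79% (1192 probe sets) without knockout array 1 and 10.1% (1766) without knockout array 2. Of the 2713, 1692 were higher and 1021 lower in the knockout arrays. With the values as deposited that split was 2646 higher and 1000 lower, and after median centring 2704 higher and 704 lower. Heterozygous array 2 stood apart on the first axis of variation. Across probe sets, heterozygous array 1 correlated with it at 0.966, and with knockout arrays 1 and 2 at 0.980 and 0.975, while heterozygous array 2 correlated with these at 0.946 and 0.975. The first principal component, with 62.8% of the variance, placed heterozygous array 2 at 33.5, heterozygous array 1 at -8.88 and the knockout arrays at -27.4 and 2.84, so it did not separate the genotypes. The second, with 26.2%, did, with the heterozygous arrays at -21.4 and -2.39 and the knockout arrays at 5.86 and 17.9. Both knockout arrays lay above or both lay below the heterozygous range for 8668 probe sets, 49.4% of those tested. Chance gives 33.3% on average. Probe sets vary together, so with so few arrays a split unrelated to genotype can also exceed that average. Among the other ways to group the arrays in pairs, that by number gave 554 probe sets, or 3.16%, at an unadjusted p under 0.05. Heterozygous array 2 with knockout array 1 against the other pair gave 156, or 0.89%. At the adjusted threshold, however, the grouping by number gave 53 and genotype 0. So few groupings cannot measure how often chance gives a share like that of genotype. Neither the 49.4% nor the 15.5% therefore shows a genotype effect beyond chance. The count past the threshold differed between settings. It was 25 after median centring, 119 with the filter at the 50th percentile, 202 with a robust variance prior and 383 with 1 probe set per gene. With the number in the labels as a replicate block it was 1308, but the labels do not say that this number marks a shared litter.

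None of the genes with the smallest p passed. Casq2, which encodes a calcium-binding protein of the sarcoplasmic reticulum, was higher by 2.45 (SE 0.16, adjusted p = 0.069, n = 2 per genotype, limma). It was the 1 gene past the threshold when X and Y were left out (adjusted p = 0.041). Ampd1, the muscle form of AMP deaminase, was higher by 1.34 (SE 0.12), Lmod3, which acts on actin filaments of muscle, by 1.12 (SE 0.10), and Atp1b4 by 1.67 (SE 0.16). Pglyrp4, a peptidoglycan recognition protein, was higher by 1.35 (SE 0.10), and Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1, by 1.08 (SE 0.10). The lower values with the smallest p were those of Sh3pxd2a (-0.82, SE 0.10), Sfrp2, a secreted Wnt modulator (-0.90, SE 0.11), Mylk4, a myosin light chain kinase (-0.98, SE 0.13), Scgb1a1, a secretoglobin (-1.21, SE 0.17), Vwa3b (-0.82, SE 0.11) and Trmt112 (-0.64, SE 0.09). Mylk4 was the 1 lower gene past the threshold after median centring (adjusted p = 0.049).

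Gene lists fixed for skin and for the clock gave higher values for metabolic, sebaceous, muscle and DNA replication genes and lower values for mitotic, interferon-induced, macrophage and antigen-presenting genes. Of the 33 lists tested with limma's camera at its preset correlation of 0.01, 7 rose and 6 fell. All 13 calls were lost when the correlation between genes was estimated, where each of these lists had adjusted p = 0.78 with an estimated correlation. With fry, which asks whether a list's genes move on balance one way, 0 lists passed, with a smallest adjusted p of 0.096. Its test for change in either direction passed 6 lists: both clock lists, oxidative phosphorylation (adjusted p = 0.032), glucocorticoid-induced genes (0.032), hair follicle stem cells (0.030) and brown adipocytes (0.015). No member of any list passed over all tested probe sets, so the counts of single members below are those adjusted over the list alone.

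Sebocyte genes, expressed by the lipid-secreting cells of the sebaceous gland, rose with a median of 0.60 (adjusted p = 1.4e-07; adjusted p = 0.78 with an estimated correlation). All 11 tested members were higher, and 9 passed when adjusted over the list alone. Awat1, an acyltransferase that makes wax esters, was higher by 1.12 (SE 0.17), Elovl3, a fatty acid elongase, by 0.82 (SE 0.11), and Scd3, a desaturase, by 0.65 (SE 0.16; 0.41 without heterozygous array 2). Fatty acid synthesis genes rose with a median of 0.23 over 16 members (adjusted p = 0.012), and cholesterol synthesis genes with a median of 0.19 over 15 members (adjusted p = 0.014), both with adjusted p = 0.78 with an estimated correlation. No member of these lists passed when adjusted over the list alone. Acss2, which makes acetyl-CoA from acetate, differed by 0.79 (SE 0.24), and Lss, lanosterol synthase, by 0.64 (SE 0.21), or by 0.41 and 0.32 without heterozygous array 2. Both lists rested on heterozygous array 2. Without it their medians were 0.00054 (adjusted p = 0.49) and 0.04 (adjusted p = 0.40), and without heterozygous array 1 they were 0.43 and 0.38. After median centring they were 0.37 and 0.33.

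Skeletal muscle genes rose with a median of 0.48 over 20 members (adjusted p = 1.7e-07; adjusted p = 0.78 with an estimated correlation). When adjusted over the list alone, 14 members rose and 1 fell. Casq1 was higher by 0.82 (SE 0.10), Mylpf, a fast-fibre myosin light chain, by 0.84 (SE 0.13), and Ckm, muscle creatine kinase, by 0.53 (SE 0.09). The member that fell was Myh7, the slow-fibre myosin heavy chain, at -0.73 (SE 0.25). Its difference was -0.34 without heterozygous array 2 and -1.11 without heterozygous array 1. Tnnt1, the slow-fibre troponin T, differed by 0.59, but by -0.17 without heterozygous array 1 and 1.35 without heterozygous array 2. The slow-fibre genes therefore did not move one way.

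Genes of oxidative phosphorylation, the mitochondrial respiratory chain and ATP synthase, rose with a median of 0.24 over 50 members (adjusted p = 2.6e-08; adjusted p = 0.78 with an estimated correlation). Of these, 45 were higher, and 10 passed when adjusted over the list alone. Sdhb, a subunit of succinate dehydrogenase, was higher by 0.75 (SE 0.10), Cyc1, cytochrome c1, by 0.75 (SE 0.11), and Ndufs3, a complex I subunit, by 0.52 (SE 0.09). Glycolysis genes rose with a median of 0.40 over 13 members (adjusted p = 0.0024; adjusted p = 0.78 with an estimated correlation), and 6 passed when adjusted over the list alone. Tpi1 was higher by 0.70 (SE 0.12), Pkm by 0.68 (SE 0.14) and Pgk1 by 0.54 (SE 0.11). The glycolysis call ended without heterozygous array 2 (median 0.27, adjusted p = 0.058), and without knockout array 1 the median was 0.25. Genes of skeletal muscle, a tissue rich in the enzymes of both pathways, were higher in the same arrays by a median of 0.48.

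The cell cycle lists went in opposite directions. Genes of G1/S and DNA replication rose with a median of 0.19 (adjusted p = 0.0049; adjusted p = 0.78 with an estimated correlation). Of 24 members, 23 were higher, and 0 passed when adjusted over the list alone. Their limma test gave 5 of the 24 members at an unadjusted p under 0.05, against 15.5% of all tested probe sets. Among the 5 were Rrm1, a ribonucleotide reductase subunit (0.36, SE 0.11), and the replicative helicase subunits Mcm2 (0.33, SE 0.12) and Mcm4 (0.38, SE 0.15). Without heterozygous array 2 these last differed by 0.22 and 0.20. Genes of G2/M and mitosis fell with a median of -0.14 (adjusted p = 4.9e-04; adjusted p = 0.78 with an estimated correlation). Of 24 members 19 were lower, and 2 passed when adjusted over the list alone: Ube2c, a ubiquitin-conjugating enzyme of mitotic exit (-0.56, SE 0.10), and Ccnb2, cyclin B2 (-0.56, SE 0.11). Mki67, the proliferation marker, did not pass (-0.50, SE 0.15). Without heterozygous array 2 the G2/M list had a median of -0.10 (adjusted p = 0.21) and without heterozygous array 1 one of -0.24. Its median was -0.07 after median centring and -0.23 with the filter at the 50th percentile, and it passed in both. The difference between the lists was not itself tested.

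Interferon-induced genes fell with a median of -0.25 over 12 members (adjusted p = 9.6e-05; adjusted p = 0.78 with an estimated correlation). Of these, 11 were lower, and 2 passed when adjusted over the list alone, Oas1a (-0.60, SE 0.13) and Ifit3 (-0.75, SE 0.17). Without heterozygous array 1 the median was -0.07 (adjusted p = 0.022), and without heterozygous array 2 it was -0.41. The list of Langerhans and antigen-presenting cells fell with a median of -0.19 over 11 members (adjusted p = 0.0047; adjusted p = 0.78 with an estimated correlation). H2-Aa, an MHC class II chain, passed when adjusted over the list alone (-0.54, SE 0.10), and Cd74, the invariant chain, did not (-0.33, SE 0.10). Without heterozygous array 1 this list had a median of -0.13 (adjusted p = 0.068). Its median was -0.35 without heterozygous array 2 and -0.35 with the filter at the 50th percentile. Macrophage genes fell with a median of -0.17 over 14 members (adjusted p = 0.013; adjusted p = 0.78 with an estimated correlation), and none passed singly. Cd68 differed by -0.65 (SE 0.18), or by -0.42 without heterozygous array 1. The macrophage call ended without heterozygous array 1 (-0.07, adjusted p = 0.24), without knockout array 1 (-0.08, adjusted p = 0.24), after median centring (-0.06, adjusted p = 0.095) and with the values as deposited (-0.10, adjusted p = 0.077). Without heterozygous array 2 the macrophage median was -0.27.

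Glucocorticoid-induced genes fell with a median of -0.16 over 13 members (adjusted p = 0.0074; adjusted p = 0.78 with an estimated correlation). The members that passed when adjusted over the list alone were the metallothioneins Mt2 (-0.75, SE 0.12) and Mt1 (-0.70, SE 0.11), which metals also induce. This call ended without heterozygous array 2 (-0.05, adjusted p = 0.17) and with the values as deposited (-0.08, adjusted p = 0.052). It held with a median of -0.05 after median centring, -0.24 without knockout array 1 and -0.09 without knockout array 2. Immediate early genes, the first to respond to a stimulus, fell with a median of -0.19 over 16 members (adjusted p = 0.013; adjusted p = 0.78 with an estimated correlation). None passed singly, and Zfp36 (-0.46, SE 0.12) had the smallest p. This call ended without heterozygous array 1 (-0.11, adjusted p = 0.068), without knockout array 1 (-0.12, adjusted p = 0.28), after median centring (-0.07, adjusted p = 0.062) and with the values as deposited (-0.10, adjusted p = 0.077).

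**Figure D2:**
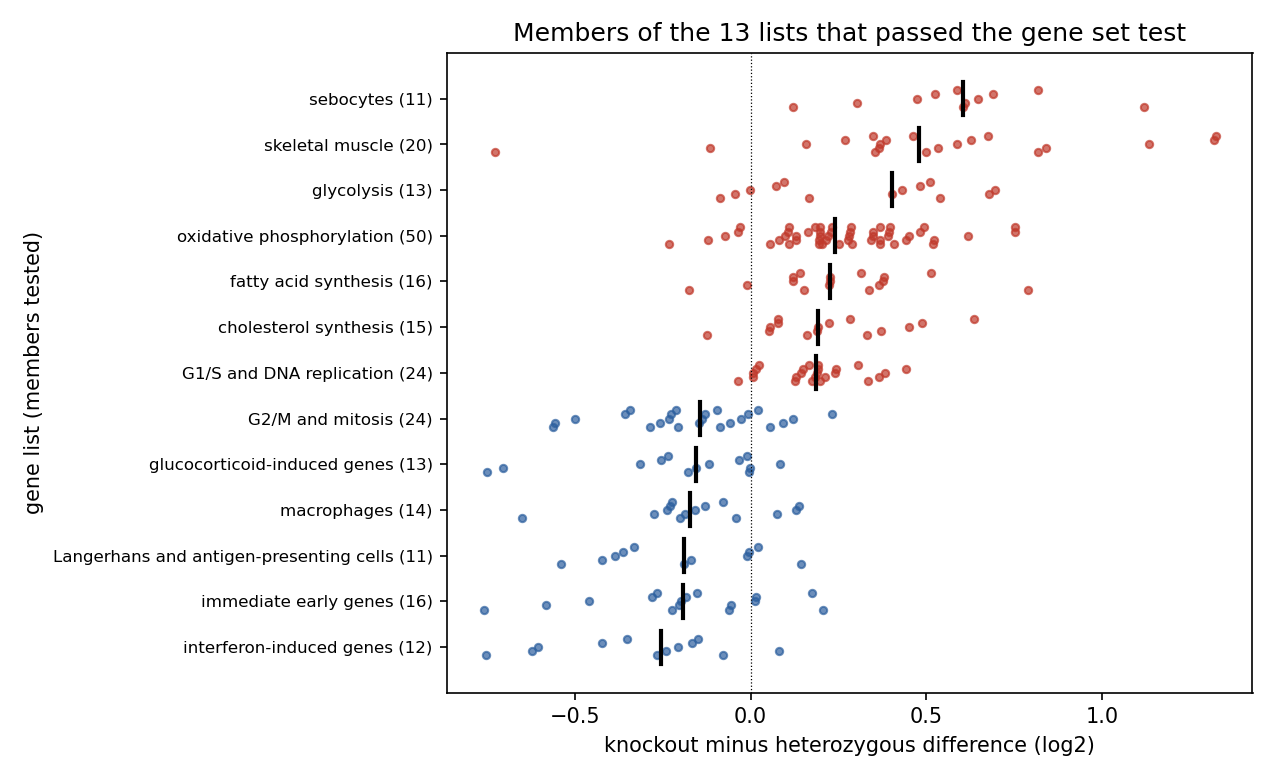
Knockout minus heterozygous difference (horizontal axis, log2) of each tested member of the 13 gene lists that passed camera with its preset correlation, by list (vertical axis, with the number of members tested). Points are genes, red in lists that rose and blue in lists that fell, and black bars are list medians, which run from -0.25 for interferon-induced genes to 0.60 for sebocytes.

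The structural compartments of skin were not among the lists that passed camera. Median differences were 0.02 for basal keratinocytes (adjusted p = 0.85), 0.02 for differentiated epidermis (0.85), -0.0015 for hair shaft and inner root sheath (0.76), -0.08 for hair follicle stem cells and hair germ (0.13), -0.02 for melanocytes (0.33), -0.0024 for fibroblasts and matrix (0.78), 0.04 for endothelium (0.93) and 0.06 for Schwann cells (0.64). In the hair follicle stem cell list, Postn was higher (0.57) and Krt24 lower (-0.48) when adjusted over the list alone. White adipocyte genes had a median of 0.04 (adjusted p = 0.98), T cell genes -0.08 (0.22), mast cell genes -0.11 (0.32) and neutrophil genes 0.04 (0.85). Brown adipocyte genes had a median of 0.26 (adjusted p = 0.17 with camera), and 3 of 7 members passed when adjusted over the list alone, Ppargc1a, Cox8b and Cidea. Ppargc1a and Cox8b are also expressed in muscle. The erythroid list had only 2 tested members, Alas2 (0.05, but -0.26 without heterozygous array 2 and -0.05 without knockout array 2) and Slc4a1 (-0.16), and was not tested as a set. The stress lists did not pass camera either, with medians of 0.12 for nucleotide excision repair (adjusted p = 0.13), 0.12 for antioxidant defence (0.22), 0.11 for p53 targets (0.30), 0.16 for hypoxia-induced genes (0.27) and 0.13 for heat shock genes (0.13). For basal keratinocytes, differentiated epidermis, white adipocytes and endothelium, as for the E-box outputs, the median was above 0 while camera pointed down. Some of these lists passed camera in another setting. They were T cells with the values as deposited (-0.11, adjusted p = 0.041), hair follicle stem cells without knockout array 1 (-0.17, adjusted p = 0.043), brown adipocytes without a filter (0.28, adjusted p = 0.046) and with the filter at the 50th percentile (0.58, adjusted p = 0.0019), and, without a filter, nucleotide excision repair (0.12, adjusted p = 0.029) and heat shock genes (0.13, adjusted p = 0.041). The scaling turned the sign of some small medians, namely of fibroblasts, hair follicle stem cells, melanocytes and neutrophils.

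Genes next to Bmal1 on its chromosome were examined because flanking DNA can travel with a targeted allele. The 100 tested genes closest to it, 50 on either side, had a median difference of 0.0048 and did not stand apart from other genes. Their camera p was 0.59. None passed the limma threshold, and 18 (18%) had an unadjusted p under 0.05, against 15.5% of all tested probe sets. With 100 genes on either side the median was -0.05 and the camera p 0.0045. Olfactory receptor genes lie among the closest 100, and all of these were lower, from -0.71 (Olfr514) to -0.26 (Olfr714). Probe sets of this family were lower in knockout arrays in general, by a median of -0.34. Whether they gave the result with 100 genes on either side was not tested. Sex-linked transcripts were alike in the 4 arrays: Xist read between 12.3 and 12.4, and the Y-linked genes Kdm5d, Eif2s3y and Uty read 5.49 or less.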

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

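The values as deposited and the threshold of 0.10 were chosen only after the data were seen; the other settings were planned. The count of probe sets past the threshold was 0 in the main setting, and also with offsets of 16 and 64, without a filter, without a trend, with the deposited values, with all probe sets and with any 1 array left out. It was 25 (24 higher, 1 lower) after median centring, 119 (96 and 23) with the filter at the 50th percentile, 202 (157 and 45) with a robust prior, 383 (282 and 101) with 1 probe set per gene, 1 (1 higher) with X and Y left out and 77 (65 and 12) at a threshold of 0.10. The filter, the X and Y setting and 1 probe set per gene test fewer probe sets, but the counts did not follow the number tested. The filter left 11705 probe sets, 1 probe set per gene left 14945, and leaving out X and Y left 16999, while the robust prior kept all 17557. The cause was not tested. The count at an unadjusted p under 0.05 was 2713 in the main setting. With 1 array left out it ran from 1192 without knockout array 1 to 3434 without heterozygous array 1 (1766 without knockout array 2), and it was 3646 with the deposited values and 3942 with the replicate block described next. The labels do not say that a number marks a shared litter, and with only 2 pairs the arrays were not treated as paired. Same-numbered arrays did share signal: their deviations from the group means correlated at 0.62 across probe sets. With that number as a replicate block, the count was 1308 (779 higher, 529 lower), and Arntl had an adjusted p of 0.0044.

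The Arntl difference was -0.76 and past the threshold with the filter at the 50th percentile, a robust prior, 1 probe set per gene and the replicate block. It did not pass in the other settings, and ran from -0.85 to -0.68 with 1 array left out. The number of lists that passed was 0 with an estimated correlation and 0 with fry, and ran from 8 to 13 with 1 array left out (8 without heterozygous array 2). It was 16 without a filter, 14 with the filter at the 50th percentile, and 11 after median centring and with the deposited values. The 13 lists that passed kept their direction in every setting run. Sebocytes, skeletal muscle, oxidative phosphorylation, G1/S and interferon-induced genes passed in all 13 camera alternatives with the preset correlation.

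Of 493 list values under alternatives, 463 kept their sign, and of 1358 gene values 1352 did. Several settings change only the variance or which probe sets are tested, so no gene's sign could turn in them. Nor could leaving out an array turn a gene whose knockout arrays both lay on the same side of the heterozygous range. These counts therefore do not measure robustness. After median centring the sign turned for Hlf (0.017) and for the medians of hair follicle stem cells (0.036), melanocytes (0.010), fibroblasts (0.063) and neutrophils (-0.042). With the deposited values it turned for hair follicle stem cells (0.00036), fibroblasts (0.027) and neutrophils (-0.078), without a filter for hair shaft (0.0026) and neutrophils (-0.047), and with the filter at the 50th percentile for melanocytes (0.087). With 1 array left out, the range crossed 0 for medians of basal keratinocytes (-0.078 to 0.16), differentiated epidermis (-0.097 to 0.15), white adipocytes (-0.11 to 0.20), endothelium (-0.11 to 0.15), fibroblasts (-0.11 to 0.14), hair shaft (-0.096 to 0.093), melanocytes (-0.18 to 0.10), T cells (-0.11 to 0.011), Schwann cells (-0.0015 to 0.12), p53 targets (-0.0035 to 0.18), clock activators (-0.017 to 0.046) and E-box outputs (-0.012 to 0.085). It also did for Bhlhe40 (-0.083 to 0.31), Ciart (-0.42 to 0.061), Hlf (-0.28 to 0.11) and Noct (-0.035 to 0.085). The neighbours of Bmal1 had a median of -0.0083 with an offset of 64, -0.026 without a filter, -0.054 with 100 genes on either side and -0.030 to 0.037 with 1 array left out. In the main setting none of these medians or genes passed; of the neighbour settings, that with 100 genes on either side passed camera at 0.05. The cause was not tested. The arrays give no signal over background per probe set here, so what dim probe sets can show is unknown.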

Other observations

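The tests of Hox genes, of the most abundant muscle genes, and of scaling and normalization below were chosen only after the result was seen. The tests on taste and trace amine receptors, on cytochrome oxidase subunits and on imprinted genes were set before they were run. Not all their genes were unseen, because Cox7a2, Cox7a1, Cox8b and Dcn belong to lists tested earlier. The limit of 0.24 in the cytochrome oxidase test equals the median already found for the oxidative phosphorylation list. Hox genes, which mark position along the body axis, differed by paralog group, with the split into groups chosen after their values were seen. The 16 tested genes of groups 5 to 10 had a median difference of 0.36 and 15 were higher in the knockout arrays, while the 10 genes of groups 1 to 4 had a median of -0.10 and 3 were higher. Outside both, Hoxd11 differed by 0.09 (-0.13 without knockout array 1) and Hoxc13 by -0.17. Without heterozygous array 1 the Hoxc13 difference was -0.06, and without heterozygous array 2 it was -0.28. As a set, groups 5 to 10 had a camera p of 4.6e-07, but p = 0.13 with an estimated correlation. Hoxc8 was higher by 1.25 (SE 0.14), Hoxa5 by 1.20 (SE 0.12), Hoxc9 by 0.82 (SE 0.15) and Hoxa6 by 0.75 (SE 0.14). Hoxc4 differed by -0.43 (SE 0.15), or by -0.28 without heterozygous array 1 and -0.58 without heterozygous array 2. None passed limma's threshold. The medians of groups 5 to 10 and 1 to 4 were 0.30 and -0.08 with the deposited values and 0.33 and -0.04 after median centring.

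Igf2, the imprinted fetal growth factor, was higher by 1.38 (SE 0.22, adjusted p = 0.11, limma) in the knockout arrays. A hypothesis is that the network of imprinted growth genes was higher as a set. Leaving out Igf2, H19 and Mirg, 12 of 17 tested members were higher, with a median of 0.14 and a camera p of 0.0029, or p = 0.085 with an estimated correlation. Meg3 differed by 0.88 (SE 0.19), Slc38a4 by 0.74 (SE 0.10) and Grb10 by 0.49 (SE 0.10), while Peg10 differed by -0.26 (SE 0.11) and Dlk1 by -0.04 (SE 0.10). The network may therefore be higher in part, and genes within it went both ways.

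Skeletal muscle genes were higher in the knockout arrays, and both a different amount of muscle in the pieces and a change in the skin's own cells could give this. Scaling is argued against, since the list median was 0.58 after median centring and 0.54 with the deposited values. A larger share of muscle tissue would raise its abundant transcripts, and 10 of the 10 most abundant members were higher. They differed by 0.16 (Myl1, 0.07 without heterozygous array 2) to 0.82 (Casq1), but belong to the list that raised the question. Myh7 (-0.73) and Mb (-0.11) were lower, but without heterozygous array 2 they differed by -0.34 and 0.28, so they are weak evidence against it. Skin pieces from another level of the body would move Hox groups apart, and the medians of the groups above differed by 0.46, on a split picked from the same values. Neither test decides, so both stay open, as does an effect of the knockout on muscle, which was not tested.

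Oxidative phosphorylation genes were higher in the knockout arrays, and muscle mitochondria alone could be the source. Then subunits of cytochrome oxidase that non-muscle tissues use would move little. The median of Cox6a1 (0.10), Cox7a2 (0.16) and Cox8a (-0.06) was 0.097, under the 0.24 of the whole list, with SEs of 0.09 to 0.11. The muscle forms Cox6a2, Cox7a1 and Cox8b differed by 0.18, 0.26 and 0.63, so Cox6a2 rose about as much as Cox7a2. The list's other subunits of cytochrome oxidase ran from 0.10 (Cox7b) to 0.37 (Cox6b1), so values under 0.24 were not particular to the non-muscle forms. With only 3 genes a side, the test does not decide, and a change in other cells of the skin stays open.

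Olfactory receptor probe sets, which skin is not expected to express, were higher in the arrays numbered 2 by a median of 0.38 in heterozygous and 0.31 in knockout mice, and lower in knockout than in heterozygous arrays by a median of -0.34. Missing normalization is argued against as the whole cause, since 0.31 remained in the smaller of these after quantile normalization. Raised background or genomic DNA in both arrays numbered 2 may be a source, because the 48 probe sets of bitter taste and trace amine receptors were higher by 0.36 in heterozygous and 0.21 in knockout mice. These 48 were also lower in knockout than in heterozygous arrays, by a median of -0.28. A background difference would thus also run with genotype, and its part in the gene and list differences above was not tested. Probe sets of small nucleolar RNAs with 1 gene were higher in the arrays numbered 2 in heterozygous mice (median 0.24) but lower in knockout mice (-0.46). The 41 such probe sets paired with several genes had median differences of 3.27 in heterozygous and 2.98 in knockout mice. Only 73.2% and 75.6% of the 41 were higher in the arrays numbered 2. The 24 probe sets of Snord116 were all higher, by medians of 3.30 and 3.04. The shift was thus not common to all 41. Grouping the arrays by number instead of genotype gave 53 probe sets past the threshold, all higher in the arrays numbered 2. Of these, 49 were paired with several genes, and the 53 held 32 distinct sets of values, so they are not 53 separate genes. No biological explanation was tested.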
